A study of Escherichia coli with 6 samples.

How the data were processed

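Each of the 6 samples was total RNA from an MG1655 culture, hybridized alone to a custom Agilent E. coli array, and per the labels 2 arrays were made for each form of NusA. Per the labels' protocols, a 1% subculture was grown at 37 degrees Celsius to an optical density of 0.4, RNA was isolated on columns with DNase digestion. Then 500 ng was primed with random hexamers carrying a T7 promoter, transcribed to cRNA and labelled with Cy3. The labels name the second array of each group as a biological replicate and also describe pooled lysate, and they do not number the replicates, so these were numbered in the order listed and no sample was left unassigned.

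The scanner files hold intensity values that, per the file headers, Agilent Feature Extraction 11.5.1.1 background-subtracted and detrended within each array, with no scaling between arrays. Raw spot and local background intensity and other values, which are flags of 0 or 1 for spots well above background, saturated or non-uniform, were deposited in the same files by the authors. The authors' series table holds deposited log2 values, a single one per gene. How they were made is not given in the sources used here, but from the values, 5 of the 6 columns closely followed the log2 processed signal minus the 75th percentile of the array. These columns correlated with their own scanner files at r = 0.998 to 1.00, with an SD of the difference of 0.0481 to 0.19 on the log2 scale. The column of WT replicate 2 correlated with its own scanner file at r = 0.923 and more closely with R258C replicate 2 (r = 0.976). The main values were computed from the scanner files for this reason, and the deposited values were used as an alternative.

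Each array held 15744 spots, of which 15208 were gene spots for 4308 probes (1 to 4 spots each) and 77 were negative controls. The processed signal was put on the log2 scale, spots of a probe were averaged, the 75th percentile of the probes of the array was subtracted, probes well above background on at least 2 arrays were kept, and probes of a gene were averaged. This gave 4182 genes by locus tag, 4112 of them with 1 probe, and all were tested; 4046 were above background on all 6 arrays. Symbols followed the reference table for assembly ASM584v2, which matched 4180 locus tags. Only gene names and gene order were taken from it.

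A linear model with the 3 groups was fitted to all 6 arrays with limma 3.58.1 in R 4.3.3 (files were read with the data.table package, version 1.17.8), with moderated t-tests for each mutant against WT and for R258C against G181D. The residual degrees of freedom were 3 and the prior added 7.22. All p-values are 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Values are log2 differences of group means, with the standard error from limma, and n is 2 arrays per group. Gene lists written from general knowledge before the data were examined were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted over all lists and 3 comparisons, and again with an estimated correlation and with fry. Camera sets a list against the other genes, while fry tests its genes against no change. Of 37 lists 36 were tested, since only 1 of the 11 members of the list of strain construction markers was measured. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.

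Genes named with values followed a rule. It took the 10 largest called increases and decreases of each mutant against WT, and the 5 largest each way of R258C against G181D, in which both arrays of 1 group lay beyond both of the other. It always took nusA, its operon, rho, nusB and nusG, and up to 4 members of each called list with the largest change in its direction. Not all of these are printed, and list members named without values were called members. For a gene not well above background on 1 or both arrays of its dimmer group, the fold change is a lower bound (for those with 1 such array, a rule added after the values were seen), computed by raising its level on those arrays to at least the lowest level that was well above background there. For a gene saturated throughout its brighter group the fold change is itself a lower bound, and for metY, saturated on all arrays, no change could be measured. The main test, the lists, the naming rule and the alternatives were chosen before the data were examined, except for 1 alternative given in the closing part.

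The depth of the arrays was taken as the share of gene spots well above background, from 96.3% to 100%. The numbers of saturated gene spots were 68, 83, 55, 87, 202 and 191 for both arrays of WT, G181D and R258C in turn. The median raw signal of the negative controls was 21.2 and 25.1 on the WT arrays and 31.0 to 35.2 on the mutant arrays. The scripts were tested on simulated data in which, for G181D against WT with 4182 genes, 100 genes were changed by a log2 fold of 1 and 100 by 2. Of these 5 and 61 were called, with 6 false calls, so changes near a log2 fold of 1 are mostly missed at this number of arrays. In a further simulation all heat shock genes were raised by a log2 fold of 1 in G181D. Camera called 1 list in G181D against WT, that of heat shock, and 0 with an estimated correlation. That setting missed a change known to be there, so not passing with it does not decide about a list. The comparison of both mutants with WT was set against 100 simulations of unchanged groups with shared WT arrays.

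The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, no filter on dim probes, only probes above background on all arrays, and the brightest probe per gene. Others were the authors' deposited values, trend and robust options of eBayes, a block for replicate number, scan or scan day, a fit of only the compared groups, and leaving out each array in turn. With 1 array left in a group, that array is assumed to vary like the others. Each WT array was alone in its scan, so scan could not be separated from the WT comparisons. A block for scan day could be fitted and called 1925 genes in G181D against WT and 2088 in R258C against WT, as leaving out WT replicate 2 did, since that array was alone on its day. Saturated spots were kept. Spots flagged as outliers were left out of the average of their probe unless all its spots were flagged, and control spots were left out.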

Results

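Total RNA was profiled from Escherichia coli MG1655 cells that carried the gene for NusA on a plasmid after the chromosomal copy had been removed by P1 transduction. NusA binds RNA polymerase and acts in transcript elongation, termination and antitermination. The plasmid encoded wild-type NusA (WT), NusA with the G181D substitution, or NusA with the R258C substitution; these residues lie in the S1 and KH1 RNA-binding domains of the protein. Cultures were grown at 37 degrees Celsius to an optical density of 0.4. The labels name WT as the control and both substitutions as the treated sets, so the comparisons ask which transcripts differed with each altered NusA. Each of the 3 groups had 2 single-colour Agilent arrays, and 4182 genes were measured on each of the 6 arrays. The small number of arrays limits the precision of every value, and the p-values measure the spread between arrays, which the labels describe as biological replicates in one place and as pooled lysate in another.

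On each array, the spots well above background made up between 96.3% and 100% of the 15208 gene spots it held. The arrays differed in the spread of their signals. The interquartile range of log2 signal was 1.13 and 1.92 on the WT arrays, 2.94 and 3.60 on the G181D arrays, and 3.91 and 3.84 on the R258C arrays. The dimmest gene spots read higher with WT NusA, since the 1st percentile of signal was 128 and 83.9 on the WT arrays, 34.8 and 11.2 on the G181D arrays, and 11.1 and 11.5 on the R258C arrays. All arrays lay on 1 slide, but the 4 mutant arrays were read in 1 scan and each WT array in a scan of its own, that of WT replicate 2 on another day. The photomultiplier voltage was 468 for the mutant arrays and 430 and 427 for the WT arrays. The difference between WT and mutant can therefore not be told apart from that between scans. R258C against G181D was measured within a single scan, although the signal range differed between these groups as well. Replicates correlated across genes at r = 0.921 for WT, 0.927 for G181D and 0.996 for R258C, and the SD of the difference between replicates was 0.74, 0.98 and 0.26 on the log2 scale. The spread among repeated spots on an array would give 0.03, 0.04 and 0.03, which leaves open whether the arrays of a pair came from separate cultures.

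**Figure D1:**
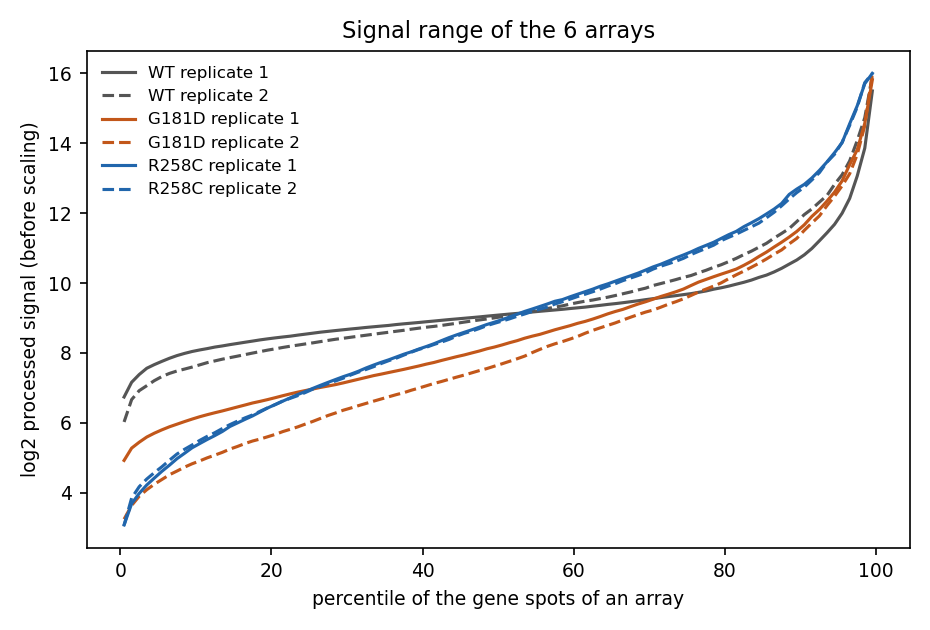
The log2 processed signal of the gene spots (vertical axis) is drawn against the percentile of the spot within its array (horizontal axis), with 1 line per array before any scaling. The lines of the WT arrays are the flattest, with interquartile ranges of 1.13 and 1.92, and those of the R258C arrays the steepest, at 3.91 and 3.84.

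Before the other genes, nusA itself (b3169) was read on every array, as log2 signal relative to the 75th percentile of the array. Its level was 1.63 and 0.91 on the WT arrays, 1.20 and 0.94 on the G181D arrays, and -0.15 and 0.02 on the R258C arrays. This level shows that nusA signal was present in each sample and does not show which allele was carried. Labelled DNA, which is left open for the WT arrays below, was not excluded as a part of this signal. With G181D, nusA was -0.20 ± 0.44 (log2, SE) relative to WT, which did not pass the test (adjusted p = 0.745, limma), and the sign of this value turned to 0.73 with median scaling and to 0.16 without WT replicate 1. With R258C, nusA fell by 1.33 ± 0.44 relative to WT (adjusted p = 0.0298). That call was lost under quantile normalization (-1.64, adjusted p = 0.0601), under median scaling (-0.30), and when WT replicate 1 (-0.98) or either R258C array (-1.25 and -1.42) was left out. Between the mutants the difference in nusA was -1.13 (adjusted p = 0.12).

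Some genes of heat shock, of pyrimidine biosynthesis and of the nusA operon, though not nusA itself, were among those that rose with G181D NusA relative to WT NusA. Their lists did not pass with an estimated correlation (adjusted p = 0.439, 0.574 and 0.574). The largest increases included clpB, which encodes a protein disaggregase, at 5.06 ± 1.03 (log2, SE, 2 arrays per group, adjusted p = 0.00528, limma). The chaperone gene dnaK followed at 4.18 ± 0.54 (adjusted p = 0.00493), with the small heat shock protein genes ibpB at 3.99 ± 0.52 and ibpA at 3.66 ± 0.53 (adjusted p = 0.00493 for both). The genes for aspartate transcarbamoylase, pyrB and pyrI, rose by 4.65 ± 0.45 and 4.47 ± 0.45 (adjusted p = 0.00294 for both). Those for carbamoyl phosphate synthetase, carA and carB, rose by 3.12 ± 0.46 and 2.89 ± 0.45 (adjusted p = 0.00493 for both). Among the decreases were the acetyl-CoA synthetase gene acs, which fell by 4.22 ± 0.81, and the manganese-repressed small protein gene mntS, which fell by 4.12 ± 0.71 (adjusted p = 0.00493 for both). The enterobactin synthesis gene entE fell by 3.93 ± 0.61 (adjusted p = 0.00493), but it turned to 1.90 with the authors' deposited values and WT replicate 1 left out, an alternative chosen after the data were seen. Without WT replicate 1 none of the calls of this comparison was left, and without WT replicate 2 those of clpB and acs were lost (adjusted p = 0.0785 and 0.0796), while the directions of all genes named here stayed with any single array left out.

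Of the 21 heat shock genes measured, 14 rose and 0 fell with G181D, counts that were the same when adjusted over the list alone. Besides those named, the chaperone and protease genes grpE, dnaJ, groL, groS, htpG, hslU, hslV, lon and clpX and the membrane protein gene fxsA were called higher. The list lay 2.99 above the median of all genes (camera adjusted p = 6.72e-16, adjusted p = 0.439 with an estimated correlation), and quantile normalization also called 14 members higher. In clpB the replicates stood far apart, with levels of 2.09 and 6.34 on the G181D arrays. The gene was saturated on G181D replicate 2, so the larger level may be too low. Its increase was 2.94 without G181D replicate 2 and 7.18 without G181D replicate 1. No heat shock call was left without WT replicate 1, but the list kept its camera call and direction with any single array left out.

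In pyrimidine biosynthesis, pyrB, pyrI, carA and carB rose, pyrE and codB fell, and 9 of the 15 genes were not called. Adjusted over the list alone, 7 rose and 2 fell (camera adjusted p = 1.46e-06, adjusted p = 0.574 with an estimated correlation). On the quantile scale 7 members rose and 0 fell. The operon of nusA showed increases on both sides of the gene. The upstream ribosome maturation gene rimP rose by 2.32 ± 0.52 (adjusted p = 0.00696). Downstream, the initiation factor gene infB rose by 2.01 ± 0.52 (adjusted p = 0.0125), rbfA, for a ribosome-binding factor, by 2.12 ± 0.48 (adjusted p = 0.00739), and truB, for a pseudouridine synthase, by 2.02 ± 0.43 (adjusted p = 0.00597). The values of rpsO (0.64) and pnp (0.52) did not pass, and the change of metY could not be measured because the gene was saturated on all 6 arrays. The list was called with 4 of 7 members higher, also adjusted over the list alone (camera adjusted p = 4.97e-06, adjusted p = 0.574 with an estimated correlation). On the quantile scale 3 of the 4 kept their call and rimP did not (1.94, adjusted p = 0.0558). The call of rimP was also lost when either WT array was left out (adjusted p = 0.108 and 0.0542), and that of infB without G181D replicate 2 (1.40, adjusted p = 0.0739). Of the single arrays left out, only WT replicate 1 ended the calls of pyrB, pyrI, carA, carB, rbfA and truB, and with the deposited values no gene was called.

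Other genes that rose in G181D included nrfA, for a formate-dependent nitrite reductase, at 3.59 ± 0.94 (adjusted p = 0.0127), and the threonine and propionate catabolic gene tdcD at 3.56 ± 0.55 (adjusted p = 0.00493). The ribosomal protein acetyltransferase gene rimL rose by 3.04 ± 0.70 (adjusted p = 0.00752). Without G181D replicate 2 the values of nrfA and rimL were 1.74 and 1.79, and without G181D replicate 1 that of nrfA was 5.44. Both calls were lost when either WT array was left out, and that of nrfA was lost on the quantile scale (adjusted p = 0.0656). The anaerobic respiration and fermentation list was called higher (camera adjusted p = 0.00762, adjusted p = 0.793 with an estimated correlation) although only 7 of 62 members rose and 18 fell, with the same counts adjusted over the list alone. Its median was -0.07, which lay 0.80 above the median of all genes, fry placed it lower without passing (adjusted p = 0.336), and the call was lost under quantile normalization (adjusted p = 0.0592). The members that rose were nrfA, the hydrogenase genes hybA, hybC and hybO, the hydrogenase maturation genes hypC and hypD, and dmsA. Formate hydrogenlyase genes (hycA to hycH) and trimethylamine oxide reductase genes (torA, torC and torD) were among those that fell. Of the termination and antitermination factors, nusG rose by 1.31 ± 0.45 (limma adjusted p = 0.0401, 0.0915 after quantile normalization). That call was lost without any single array other than WT replicate 2, and the value was 0.84 without WT replicate 1. The values of rho at 1.07 (adjusted p = 0.0664) and nusB at 1.01 (adjusted p = 0.15) did not pass.

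Genes for surface structures and iron uptake were lower with G181D than with WT. Of 52 flagellar and chemotaxis genes 39 fell and 0 rose (41 and 0 adjusted over the list alone). Among them were fliN at -3.05, cheR at -2.73, cheW at -2.72 and fliJ at -2.71 (adjusted p = 0.00493 for each). The list itself was called lower (camera adjusted p = 1.91e-05, adjusted p = 0.597 with an estimated correlation). Iron acquisition, which includes the enterobactin genes, had 34 of 40 members lower (35 lower and 1 higher adjusted over the list alone, camera adjusted p = 6.17e-05, adjusted p = 0.81 with an estimated correlation). Its members entS, fepC and fepG stood at -3.53, -3.75 and -3.50. In colanic acid synthesis 20 of 21 genes fell, the same number adjusted over the list alone (camera adjusted p = 5.22e-05, adjusted p = 0.793 with an estimated correlation). In fimbriae and curli 21 of 28 fell (22 adjusted over the list alone, camera adjusted p = 0.00344, adjusted p = 0.81 with an estimated correlation). The prophage group of CP4-44, CP4-57, CPS-53 and CPZ-55 had 30 of 49 members lower (32 adjusted over the list alone, camera adjusted p = 0.0179, adjusted p = 0.835 with an estimated correlation, 0.601 after quantile normalization). After quantile normalization the numbers of lower and higher members were 9 and 2 for flagella, 14 and 0 for iron acquisition, 9 and 0 for colanic acid, 5 and 0 for fimbriae, and 11 and 6 for the prophages. No member of these lists was called without WT replicate 1. With the deposited values and WT replicate 1 left out, cheR (1.42), cheW (0.81), entS (2.93), fepC (1.29) and fepG (1.36) turned, while fliN (-2.89) and fliJ (-2.60) did not. The groups move with the narrow signal range of the WT arrays: of the 1046 dimmest genes, 900 were called lower and 0 higher.

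Several lists were placed above other genes by camera with few members called. For ribosomal proteins 1 of 53 genes rose and 1 fell (camera adjusted p = 1.59e-05, adjusted p = 0.804 with an estimated correlation), and on the quantile scale the direction of camera turned to lower without passing (adjusted p = 0.298). For translation factors and aminoacyl-tRNA synthetases, 2 of 32 genes rose and 1 fell (camera adjusted p = 0.000897, adjusted p = 0.597 with an estimated correlation, 0.0471 after quantile normalization). The initiation factor genes infC and infA rose by 1.90 and 1.58 (adjusted p = 0.0283 and 0.0184). Envelope stress genes rose in 3 of 29 cases and fell in 1 (camera adjusted p = 0.00168, adjusted p = 0.574 with an estimated correlation, 0.033 after quantile normalization). The phage shock genes pspB and pspC rose by 1.73 and 1.34 and the anti-sigma factor gene rseA by 1.52. Without WT replicate 1 none of these calls was left, and infC was then 1.06. The call of infC was also lost on the quantile scale and without G181D replicate 2, and that of infA without G181D replicate 2 or any R258C array. That of pspC was lost with any array other than G181D replicate 2 left out, and that of rseA on the quantile scale and with any array other than G181D replicate 1 left out (0.72 without G181D replicate 2). In the transcription machinery list 2 of 15 genes rose and 1 fell (camera adjusted p = 0.00223). The RNase list had 1 of 19 members called in each direction (camera adjusted p = 0.0262), and histidine biosynthesis had 0 of 9 called (camera adjusted p = 0.0324). Each of these had an adjusted p of 0.574 with an estimated correlation and lost the call on the quantile scale. Adjusted over the list alone, none of these lists had a called member.

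In all, limma called 137 genes higher and 1590 lower in G181D than in WT, so that 7.93% of the calls were increases, and the median of all genes was -0.88. The 1046 brightest genes held 111 of these increases and had a median of 0.26. With quantile normalization the split was 362 higher and 438 lower (45.2% increases), and with median scaling it was 585 and 775. Without WT replicate 1 limma called 0 genes (1501 at an unadjusted p under 0.05), and without G181D replicate 2 it called 882. From the authors' deposited values, in which WT replicate 2 departed from its scanner file, it called 0 (187 at an unadjusted p under 0.05). When WT replicate 1 was left out of the deposited values as well, limma called 0 genes (970 at an unadjusted p under 0.05). The heat shock, pyrimidine and flagellar lists then kept their calls and directions, the nusA operon list lost its call (adjusted p = 0.294), and the direction of camera turned to higher for colanic acid (adjusted p = 0.000782) and iron acquisition (adjusted p = 0.0811).

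In cells with R258C NusA the largest called increases relative to WT were those of rbsR, nrdG and rho. The repressor gene of the ribose operon, rbsR, rose by 2.20 ± 0.46 (adjusted p = 0.00279, limma) and the ribokinase gene rbsK by 1.97 ± 0.52 (adjusted p = 0.0098). The value of rbsK was 1.23 without WT replicate 1, and its call was lost without R258C replicate 1 (adjusted p = 0.0521) and on the quantile scale (adjusted p = 0.072). The anaerobic ribonucleotide reductase activating gene nrdG rose by 2.19 ± 0.43 (adjusted p = 0.00193) and rho, for the termination factor, by 2.09 ± 0.43 (adjusted p = 0.00248). The decreases were larger. The nitrate and nitrite transporter gene narU fell at least 51.5-fold (adjusted p = 0.000161), the enterobactin-region gene fepE at least 50.9-fold and the predicted phosphatidyltransferase gene ynbA at least 35.6-fold (adjusted p = 0.000156 for both). These are bounds because the genes were not well above background on either R258C array. The ureidoglycolate lyase gene allA fell at least 42.2-fold and the phenylacetate degradation gene paaZ at least 51.3-fold (adjusted p = 0.000156 for both), bounds because these genes were not well above background on R258C replicate 2. These decreases depend on the WT values, and the bounds hold only for the WT signal of the scanner files. With the authors' deposited values and WT replicate 1 left out, narU, fepE and allA were -0.96, -0.12 and -1.56. There ynbA and paaZ turned to 0.40 and 0.17. In the same alternative, chosen after the data were seen, rbsR, nrdG and rho were 1.56, 2.24 and 1.92.

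Aerobic respiration and ATP synthase genes had 7 of 31 members higher and 0 lower with R258C (0 adjusted over the list alone, camera adjusted p = 3.16e-14, adjusted p = 0.597 with an estimated correlation). The list lay 2.01 above the median of all genes, which was -0.89. Increases followed signal level: the 1046 brightest genes had a median of 0.45 and held 36 of the 42 increases. The 1046 dimmest had a median of -3.42 and held 0. How far brightness sets the place of a list among all genes was not tested. The genes that rose were nuoC at 1.69 ± 0.60 (adjusted p = 0.0414), nuoL at 1.69 ± 0.62 (adjusted p = 0.0486) and nuoE at 1.47 ± 0.54 (adjusted p = 0.0483), with nuoH, nuoI, atpA and atpH. The WT replicates lay apart here: nuoC and nuoL stood at 0.84 and 0.75 without WT replicate 1, and at 2.55 and 2.63 without WT replicate 2. With the deposited values and WT replicate 1 left out, nuoC, nuoL and nuoE were 0.39, 0.36 and 0.33. No member passed when WT replicate 1 or either R258C array was left out, and nuoL did not pass without either G181D array (adjusted p = 0.052). On the quantile scale 1 member was called and the list kept its call (adjusted p = 0.00133). Camera also placed the ribosomal protein list above other genes (adjusted p = 1.54e-12, adjusted p = 0.597 with an estimated correlation), with 0 of 53 members higher and 1 lower (0 and 0 adjusted over the list alone). The same held for the tricarboxylic acid cycle list (adjusted p = 1.46e-06, adjusted p = 0.597 with an estimated correlation), with 0 of 19 members called in either direction by either adjustment. Both calls were lost under quantile normalization (adjusted p = 0.298 and 0.307). In the transcription machinery list, rho and the RNA polymerase subunit gene rpoB (1.34 ± 0.49, adjusted p = 0.0478) rose (1 gene adjusted over the list alone, camera adjusted p = 3.52e-06, adjusted p = 0.574 with an estimated correlation). That list call was lost on the quantile scale (adjusted p = 0.0539), as were the calls of rho (1.49, adjusted p = 0.051) and rpoB (adjusted p = 0.133). With single arrays left out, rho kept its call throughout, at 1.99 to 2.18, and rpoB lost it without WT replicate 1 (0.74) and when either R258C array was left out.

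The nusA operon list was called higher in R258C by camera (adjusted p = 0.00951, adjusted p = 0.574 with an estimated correlation). However, 0 of its 7 members, which include the saturated metY, were called by either adjustment and the list call was lost on the quantile scale (adjusted p = 0.541). The value of rimP was 0.00 ± 0.52 (adjusted p = 0.996), or -0.43 on the quantile scale. Heat shock genes, which rose in G181D, had 0 of 21 members higher and 3 lower in R258C against WT (ibpB, degP and rpoH, named after their values were seen; 0 and 2 adjusted over the list alone). Quantile normalization left none of these decreases and turned degP to 0.73. Against a median of all genes of -0.89, camera placed the list above other genes while fry placed it lower without passing (adjusted p = 0.384, camera adjusted p = 0.013, adjusted p = 0.574 with an estimated correlation, 0.395 after quantile normalization).

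Many dim genes were lower in R258C than in WT. All 21 colanic acid genes fell (21 adjusted over the list alone, camera adjusted p = 1.46e-06, adjusted p = 0.676 with an estimated correlation), with wzxC at -5.09 and wcaD lower at least 19.2-fold (adjusted p = 0.000156 and 0.000157). Iron acquisition had 31 of 40 members lower (34 adjusted over the list alone, camera adjusted p = 0.000301, adjusted p = 0.81 with an estimated correlation), including entE at -5.86 and entB at -5.33. In fimbriae and curli 18 of 28 fell (20 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.00557, adjusted p = 0.81 with an estimated correlation). Acid resistance genes were lower in 12 of 17 cases (13 adjusted over the list alone, camera adjusted p = 0.00937, adjusted p = 0.793 with an estimated correlation). The outer membrane lipoprotein gene slp stood at -5.05 and the lysine antiporter gene cadB at -3.75 (adjusted p = 0.000156 and 0.000223). After quantile normalization these lists kept their calls, with 9, 9, 6 and 3 members lower and 1, 0, 0 and 0 higher. With the deposited values and WT replicate 1 left out, wzxC (0.13) and entB (0.19) turned, and wcaD, entE, slp and cadB were -0.61, -0.04, -0.59 and -1.79.

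Prophage genes were lower in 13 of 16 cases for DLP12 (13 adjusted over the list alone, camera adjusted p = 0.0234), and 17 of 22 for Rac (17, adjusted p = 0.00575). They were lower in 20 of 25 cases for Qin (21, adjusted p = 0.00727) and 38 of 49 for the group of CP4-44, CP4-57, CPS-53 and CPZ-55 (38, adjusted p = 0.000879). With an estimated correlation each adjusted p was between 0.804 and 0.81. The lists of e14 (12 of 19 lower, camera adjusted p = 0.12) and CP4-6 (16 of 24 lower, camera adjusted p = 0.0571) did not pass. The e14 counts and tests, here and below, include the tRNA gene argU, which was not written in the list and entered through a shared name. Examples were dicC in Qin, lower at least 40.2-fold, and ylcG in DLP12 at -5.16 (adjusted p = 0.000171 and 0.000156). Genes silenced by H-NS, a nucleoid protein, had 17 of 26 members lower (18 adjusted over the list alone, camera adjusted p = 0.0283, adjusted p = 0.81 with an estimated correlation). Phosphate starvation genes were lower in 16 of 19 cases (16 adjusted over the list alone, camera adjusted p = 0.0262, adjusted p = 0.81 with an estimated correlation), including phnD at -5.73. On the quantile scale the DLP12 call stayed (camera adjusted p = 0.00386) and CP4-6 was called lower (camera adjusted p = 0.000566). The calls of Rac, Qin, the group with CP4-44, the H-NS genes and the phosphate genes were lost. The numbers of lower and higher members were then 6 and 1 for DLP12, 3 and 4 for Rac, 2 and 3 for Qin, and 11 and 4 for the group with CP4-44. They were 1 and 3 for the H-NS genes and 5 and 2 for the phosphate genes. For Qin and H-NS the direction of camera turned to higher without passing (adjusted p = 0.89 and 0.625), although neither median lay above that of all genes. The example genes ylcG and phnD kept their calls with smaller values of -3.69 and -3.81. With the deposited values and WT replicate 1 left out, ylcG, phnD and dicC were -0.38, -0.48 and -0.37. These groups too move with the narrow range of the WT arrays: of the 1046 dimmest genes 1007 were called lower and 0 higher.

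Camera also placed 3 lists above other genes in which no member rose. Translation factors had 2 of 32 members lower (2 adjusted over the list alone, camera adjusted p = 2.79e-05, 0.0122 after quantile normalization). Methionine and cysteine biosynthesis had 3 of 30 lower (3, camera adjusted p = 0.000488, 0.0309 after quantile normalization), and RNases 2 of 19 (2, camera adjusted p = 0.00549, 0.288 after quantile normalization). Each had an adjusted p of 0.574 with an estimated correlation, and fry placed the latter pair lower without passing (adjusted p = 0.746 and 0.742).

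In R258C against WT limma called 42 genes higher and 1757 lower (2.33% increases). Quantile normalization gave 233 and 343 (40.5% increases), with 59 of the calls in the opposite direction to those above, and median scaling gave 746 and 1197. Without WT replicate 1 the count was 1151, and from the authors' deposited values limma called 0 genes (65 at an unadjusted p under 0.05), and 0 again when WT replicate 1 was left out of them too (147). In that last setting the call of the respiration list was lost (adjusted p = 0.621), the iron acquisition list was called higher (adjusted p = 0.00935) and the acid resistance list kept its call.

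Between the mutants, whose 4 arrays were read in 1 scan, camera called lists of aerobic respiration, the tricarboxylic acid cycle and flagella higher in R258C, and of heat shock and pyrimidine synthesis lower. None of these lists passed with an estimated correlation. Compared with G181D, R258C cells had more transcript of acs at 5.65 ± 0.81 (log2, SE, adjusted p = 0.00992, limma) and of thrA, for an aspartokinase of threonine synthesis, at 3.73 ± 0.49 (adjusted p = 0.0075). They also had more of mntS, at 3.70 ± 0.71 (adjusted p = 0.0262), and of the proline utilization gene putA, at 3.59 ± 0.52 (adjusted p = 0.00992). The carbon starvation gene cstA was at least 12.1-fold higher (adjusted p = 0.00349), a bound because its spots were saturated on the R258C arrays. Lower in R258C were ibpB, which fell by 6.16 ± 0.52 (adjusted p = 0.00101), and pyrB and pyrI, which fell by 4.87 ± 0.45 and 4.66 ± 0.45 (adjusted p = 0.00133 for both). In the same direction ibpA fell by 4.65 ± 0.53 (adjusted p = 0.00349) and clpB fell by 4.39 ± 1.03 (adjusted p = 0.0372). Without G181D replicate 2 the value of clpB was -2.27 and that of mntS 2.38, and on the quantile scale the calls of both were lost (adjusted p = 0.173 and 0.102). When either WT array was left out none of the calls of this comparison was left, with unchanged values and adjusted p values of 0.0634 to 0.129 for the genes named here.

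**Figure D2:**
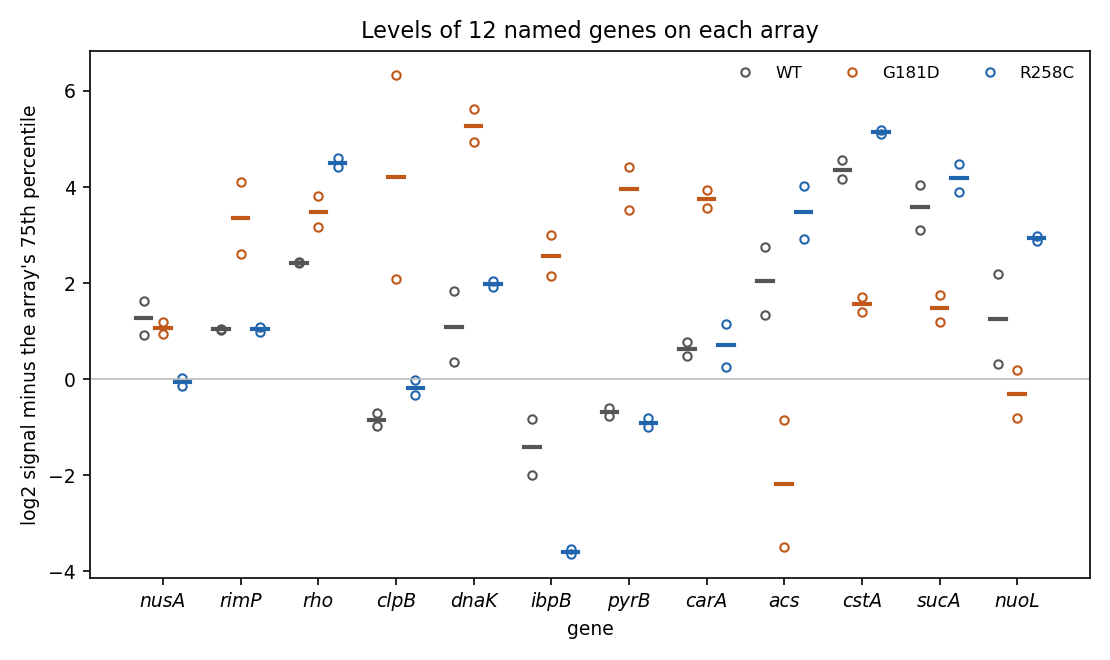
Points give the log2 signal relative to the 75th percentile of the array (vertical axis) for 12 named genes on each of the 6 arrays, and bars give the mean of the 2 arrays of a group. For clpB, dnaK, ibpB, pyrB and carA both G181D points lie above all others, and for acs, cstA, sucA and nuoL both G181D points lie below all others.

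Tricarboxylic acid cycle genes were higher in R258C than in G181D in 8 of 19 cases and lower in 0 (13 and 0 adjusted over the list alone, camera adjusted p = 1.54e-12, adjusted p = 0.574 with an estimated correlation). The list lay 2.47 above the median of all genes. The succinate dehydrogenase gene sdhB rose by 2.90 ± 0.62 (adjusted p = 0.0308), the oxoglutarate dehydrogenase gene sucA by 2.72 ± 0.48 (adjusted p = 0.0226) and sucC by 2.67 ± 0.56 (adjusted p = 0.0286). Aerobic respiration and ATP synthase genes were higher in 9 of 31 cases (14 adjusted over the list alone, camera adjusted p = 3.1e-14, adjusted p = 0.597 with an estimated correlation). They were nuoG, nuoI, nuoK, nuoL (3.26 ± 0.62, adjusted p = 0.026), nuoM, nuoN, cyoB, cyoC (2.85 ± 0.49, adjusted p = 0.0192) and cyoD. Flagellar and chemotaxis genes were higher in 8 of 52 cases (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 5.49e-08, adjusted p = 0.574 with an estimated correlation). Among them fliN rose by 2.19 and fliK by 2.06 (adjusted p = 0.0288 and 0.0268). Of the genes given with values, quantile normalization ended the calls of sdhB, sucC, nuoL, fliN and fliK and left those of sucA and cyoC. It called 0 of the 52 flagellar and chemotaxis genes. Every gene named here lost its call when either WT array was left out. Among those with values, so did sdhB, sucA, sucC and cyoC without R258C replicate 2, and sdhB, sucC and nuoL without G181D replicate 2. The same held for sucC without G181D replicate 1, and for fliN and fliK without either R258C array.

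Heat shock genes were lower in R258C than in G181D in 12 of 21 cases and higher in 0 (15 and 0 adjusted over the list alone, camera adjusted p = 6.31e-07, adjusted p = 0.574 with an estimated correlation). The gene htpG, for a chaperone of the Hsp90 family, fell by 3.47 ± 0.43 (adjusted p = 0.00508). On the quantile scale 5 heat shock genes were called lower and 0 higher. Pyrimidine biosynthesis genes were lower in 7 of 15 cases (12 adjusted over the list alone, camera adjusted p = 1.46e-06, adjusted p = 0.574 with an estimated correlation): pyrB, pyrI, pyrD, carA, carB, codA and upp. Acid resistance genes were lower in 6 of 17 cases (12 adjusted over the list alone, camera adjusted p = 3.58e-05, adjusted p = 0.597 with an estimated correlation). Here cadB stood at -3.73 and the regulator gene gadX at -2.29 (adjusted p = 0.0075 and 0.0267). On the quantile scale 1 acid resistance gene was called lower and 0 higher. Anaerobic respiration genes fell in 6 of 62 cases (22 adjusted over the list alone, camera adjusted p = 0.000221, adjusted p = 0.637 with an estimated correlation), with the nitrite transport and reduction genes nirB, nirC and nirD among them. General stress genes fell in 3 of 31 cases (7 adjusted over the list alone, camera adjusted p = 0.00212, adjusted p = 0.574 with an estimated correlation), with osmB at -3.72 (adjusted p = 0.0075). The call of gadX was lost on the quantile scale (adjusted p = 0.0663) and without either R258C array, those of carA and carB were lost without R258C replicate 1, and all calls were lost when either WT array was left out. In the nusA operon rimP fell by 2.32 ± 0.52 (adjusted p = 0.0342), a call lost on the quantile scale (adjusted p = 0.124), without WT replicate 1 or 2, without R258C replicate 1 or 2, and without G181D replicate 1. The values of truB, rbfA and infB, at -1.28, -1.49 and -0.99, did not pass.

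Camera also called lists of some prophages and of colanic acid synthesis lower in R258C than in G181D, but not those of the prophages e14 (0 of 19 called, adjusted p = 0.546) and CP4-6 (0 of 24 called, adjusted p = 0.405). In DLP12 6 of 16 members fell (8 adjusted over the list alone, camera adjusted p = 0.00164, adjusted p = 0.668 with an estimated correlation, 0.000566 after quantile normalization). In Rac 2 of 22 fell (6, camera adjusted p = 0.0198) and in Qin 3 of 25 fell and 1 rose (12 and 1, camera adjusted p = 0.0218). In the group of CP4-44, CP4-57, CPS-53 and CPZ-55 7 of 49 fell (11, camera adjusted p = 0.0167). Each of these had an adjusted p of 0.835 with an estimated correlation. In colanic acid synthesis 1 of 21 fell (12, camera adjusted p = 0.000519, adjusted p = 0.81 with an estimated correlation). All of these but DLP12 lost their calls on the quantile scale. Dim genes as a whole were lower in this comparison, and the median log2 change of the 1046 dimmest genes was -1.16. On the higher side, cold shock genes were higher in R258C than in G181D in 3 of 16 cases (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0189, adjusted p = 0.574 with an estimated correlation, 0.0563 after quantile normalization). The cold shock protein genes cspG and cspB rose by 3.01 and 2.19 and the helicase gene deaD by 2.10. The calls of cspB and deaD were lost on the quantile scale (adjusted p = 0.103 and 0.173), without G181D replicate 2 (1.56 and 1.30) and when either R258C array was left out, and all calls here were lost when either WT array was left out. Ribosomal proteins (0 of 53 called, camera adjusted p = 3.52e-06, adjusted p = 0.793 with an estimated correlation) and methionine and cysteine biosynthesis (0 of 30, camera adjusted p = 0.000244, adjusted p = 0.574) had no member called by either adjustment. Both kept their list calls on the quantile scale (adjusted p = 0.000566 and 0.0122). Transcription machinery had 1 of 15 members higher (2 adjusted over the list alone, camera adjusted p = 0.00642). Branched-chain amino acid biosynthesis had 3 of 19 higher and 1 lower (5 and 2, camera adjusted p = 0.0416), and translation factors 1 of 32 higher (1, camera adjusted p = 0.0474). These had an adjusted p of 0.597, 0.597 and 0.793 with an estimated correlation and lost their calls on the quantile scale.

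**Figure D3:**
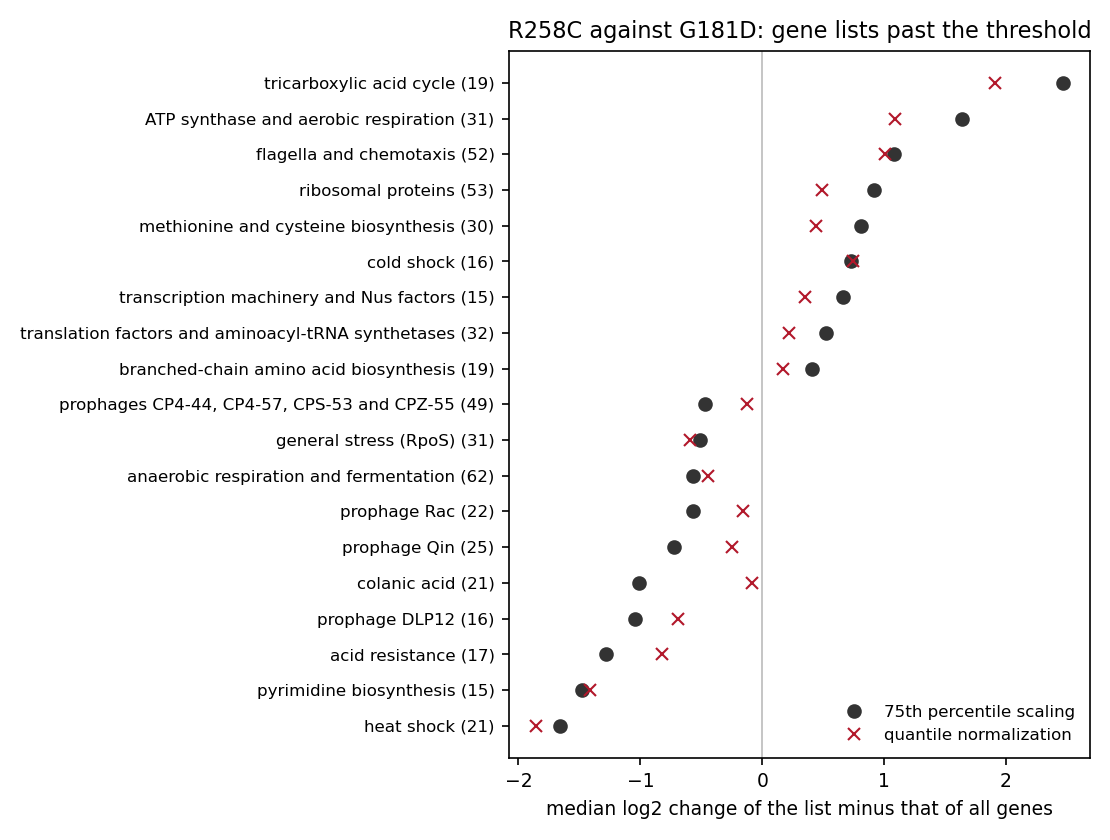
The median log2 change of each gene list called by camera in R258C against G181D, minus the median of all genes, is on the horizontal axis for 75th percentile scaling (circles) and quantile normalization (crosses). The tricarboxylic acid cycle list lies highest at 2.47 and the heat shock list lowest at -1.66, and every list keeps its side of 0 with both scalings, although 8 lists lose their call under quantile normalization.

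For this comparison limma called 86 genes higher and 177 lower (32.7% increases), with a median of all genes of -0.37, and quantile normalization called 19 and 16 (54.3% increases). At an unadjusted p under 0.05 there were 1232 genes. The calls followed signal level here too, and the G181D arrays had the narrower signal range. The 1046 dimmest genes had a median of -1.16 and held 97 of the 177 lower calls. The 1046 brightest had a median of 0.12 and held 55 of the 86 higher calls. A limma fit of the 4 arrays of the scan alone called 0 genes (1411 at an unadjusted p under 0.05), with a lowest adjusted p of 0.0634. The same count of 0 followed when either WT array was left out, because these arrays add to the estimate of the spread. Within the scan the list tests gave camera adjusted p values of 7.41e-12 for the tricarboxylic acid cycle, 9.14e-15 for aerobic respiration, 3.52e-07 for flagella, 1.59e-05 for heat shock, 0.000129 for pyrimidine synthesis and 0.000262 for acid resistance. With an estimated correlation none of them passed, with adjusted p values of 0.478 to 0.562. Leaving out either R258C array gave 75 and 52 called genes, and the authors' deposited values gave 0 (234 at an unadjusted p under 0.05).

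The fold changes of both mutants against WT correlated across the 4182 genes at r = 0.794, and 81.7% of genes had the same sign, although genes are not independent replicates. Simulated unchanged groups that shared the same WT arrays gave a mean r of 0.5 (highest 0.539) and the same sign for 66.7% of genes, and the covariance was 1.69 against 0.125 in the simulations. Both comparisons called 9 genes higher and 1309 lower, where independent lists of these sizes would share 1.38 and 668 and the simulations gave 0.07 shared calls on average. The simulations drew noise for each gene on its own, so they hold the sharing of the WT arrays but not their narrow signal range. Of the 1046 dimmest genes, 900 were called lower in G181D and 1007 in R258C. A shared response of the mutants can therefore not be told apart from the narrow range of the shared WT arrays, which are too few to be split. Without WT replicate 1 the number of genes called in both was 0, since G181D against WT then had no calls, and without G181D replicate 2 it was 714. Quantile normalization gave r = 0.775 with 151 genes higher and 244 lower in both, and the authors' deposited values gave r = 0.478 with 0 shared calls.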

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

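All alternatives were chosen before the data were examined except the deposited values with WT replicate 1 left out too, which was added after WT replicate 2 of the deposited values was seen to depart from its scanner file.

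In the WT comparisons no gene was called from the deposited values, nor, in G181D against WT, without WT replicate 1, and quantile normalization lowered the counts less. The calls of R258C against G181D depend on the WT arrays for the estimate of the spread. Some lists kept their direction and camera call with every array left out in turn and under quantile normalization. In G181D against WT these included heat shock, pyrimidine biosynthesis and flagella. In R258C against G181D they included the tricarboxylic acid cycle, aerobic respiration, flagella, heat shock, pyrimidine biosynthesis and acid resistance. No list passed with an estimated correlation, a setting that also missed the list changed in the simulated data. Of 20, 20 and 21 alternatives for the number of genes called in G181D against WT, R258C against WT and R258C against G181D, 15, 16 and 7 stayed within 1.5 times the count. These are not independent checks. No filter and a 2-fold minimum could change nothing, as all 4182 genes passed the filter and every call was at least 2-fold. For R258C against G181D, leaving out either WT array, fitting only the compared groups and blocks for scan or scan day amount to the same fit. Of 16 each, 12 kept the sign of the nusA value in G181D, which was called in none of them, and 9 kept both sign and call of that in R258C. The correlation of the mutants stayed above 0.519, the 95th percentile of the simulated unchanged groups, in 14, and the number of genes called in both stayed within 1.5 times the main count in 11. Of 18 each, 15, 14 and 15 left the number of called lists within 1.5 times the 15, 19 and 19 of the main settings. Genes dimmer than background on an array are limited to bounds, and changes near a log2 fold of 1 are limited by the number of arrays.

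The number of genes called was 800, 576 and 35 (in the order above) under quantile normalization and 0, 0 and 0 from the deposited values. For R258C against G181D it was 814 with normexp, 402 with median scaling, 692 with trend and robust options and 851 with a replicate block. It was 0 with only the compared groups, with scan as a block or with scan day as a block, where the WT arrays no longer add to the estimate of the spread. With single arrays left out the counts were 0 to 2096, 1151 to 2088 and 0 to 358. The nusA value in G181D turned to 0.73 with median scaling and 0.31 from the deposited values, with a range of -0.56 to 0.16 with single arrays left out, where 0.16 came without WT replicate 1. In R258C it was -1.64 with quantile normalization, -0.30 with median scaling and -0.85 from the deposited values, none of them called, and -1.69 to -0.98 with single arrays left out. The correlation of the mutants was 0.478 from the deposited values and 0.688 to 0.862 with single arrays left out. Genes called in both numbered 395 under quantile normalization, 0 from the deposited values and 0 to 1631 with single arrays left out. Apart from the fits with fewer arrays for the spread, the cause was not tested.

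Called lists numbered 0, 0 and 0 with an estimated correlation and 7, 12 and 5 with fry. Fry called 2 lists higher and 5 lower in G181D against WT, and only lower ones in the other comparisons. The 2 higher were heat shock and the nusA operon (fry adjusted p = 0.0417 for both). Heat shock was lower between the mutants (fry adjusted p = 0.0417). In R258C against WT fry also called lists that camera did not, among them general stress and flagella, both lower. Lists called by camera numbered 10 for R258C against WT and 12 for R258C against G181D under quantile normalization, and 8 for G181D against WT from the deposited values. With single arrays left out they numbered 12 to 17, 18 to 20 and 14 to 21. With the added alternative 0, 0 and 0 genes were called (970, 147 and 1357 at an unadjusted p under 0.05), the nusA values were 1.14 and -0.0174, the correlation was 0.311, genes called in both were 0, and 9 lists were called in R258C against WT. In it 20 of 54 called values of named genes in G181D against WT and 14 of 61 in R258C against WT had the opposite sign, and 0 of 52 in R258C against G181D, and genes near background are among those of R258C against WT. The cause was not tested.

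Among the named genes, and without the added alternative given above, 1930 of 2475 alternative values of called genes kept direction and call, 544 kept only the direction and 1 turned. Of 1361 values of uncalled genes 1136 stayed uncalled, 214 became called and 11 turned. The fit with no filter on dim probes, which could not differ, gave 167 values of called and 91 of uncalled genes that stayed the same. Among those that turned was rimP in R258C against WT, which was -0.0446 with normexp, -0.43 with quantile normalization, -0.15 from the deposited values, and -0.0535 to 0.0607 with single arrays left out. With single arrays left out clpP in R258C against WT was -0.0384 to 1.52 and pnp in R258C against G181D was -0.0771 to 0.381. The rest of those that turned show no change of direction, as their readings are not exact. The gene metY was saturated on all 6 arrays, so its readings of 0.10 in R258C against WT with median scaling, and of -0.0838 to 0.436 in G181D against WT with single arrays left out, do not measure a change. The genes racC, yfdN and wcaF were not well above background on 1 or both R258C arrays, so their readings of 0.19, 0.10 and 0.25 in R258C against G181D with quantile normalization allow only bounds. The cause was not tested. The differences between the second and the first replicate correlated between groups at r = 0.25 for WT and G181D, -0.0859 for WT and R258C, and -0.257 for G181D and R258C, so the replicate numbers were not taken as pairs. A block for them called 1926, 1921 and 851 genes.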

Other observations

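The tests of the scanner offset, of transcription in WT cells, of the deposited WT replicate 2 values and of the heat shock and pyrimidine lists were chosen only after the result was seen, and so were the genes named in the next paragraph.

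Against WT, 7 genes were called in opposite directions in the mutants by limma. The small heat shock protein gene ibpB was 3.99 in G181D and -2.18 in R258C, the regulator gene appY was 1.55 and -2.66, the nucleoside transporter gene nupG was 1.25 and -1.50, and the phage shock gene pspC was 1.34 and -1.20. In the other direction were the glutamate and aspartate transport genes gltK, at -1.72 and 1.40, and gltL, at -1.50 and 1.36, and ybdD, of the region of the starvation gene cstA, at -1.23 and 1.31. Some of these depend on the scaling. Quantile normalization turned the R258C value of appY to 0.48 and left -0.11 for ibpB, -0.38 for nupG and -0.87 for pspC, and it left -0.22 for gltL in G181D. Called higher in both mutants were 9 genes, a number that was 0 without WT replicate 1 and when either R258C array was left out. Among them were the cyclopropane fatty acid synthase gene cfa, at 2.50 and 1.83, the fatty acid synthesis gene fabF, at 1.95 and 1.66, the guanylate kinase gene gmk, at 1.30 and 1.36, and the hydrogenase maturation gene hybG, at 1.48 and 1.66. The R258C call of cfa was also lost on the quantile scale (adjusted p = 0.0741, limma).

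The dimmest genes read higher on the WT arrays than on the mutant arrays. An offset of the scanner was argued against by the negative control spots, whose raw signal was no higher than 25.1 on the WT arrays and at least 31.0 on the mutant arrays. Genomic DNA labelled along with the RNA could raise dim genes near the replication origin most. For this, the 1043 genes dimmest in the mean of the mutant arrays were taken. Those nearest the origin in gene order lay above those farthest from it by 0.355 and 0.317 on the WT arrays (permutation p = 1e-04 for both, the smallest that 10000 permutations can give). On the mutant arrays the difference was 0.151, 0.142, 0.119 and 0.17 (permutation p = 9e-04, 0.0338, 0.147 and 0.0342). The permutations count neighbouring genes as independent, so these p-values measure the spread among genes and not between arrays or cultures. The choice of genes by their mutant values limits the spread on these arrays, so the sizes are not directly comparable with those of WT. The bounds set beforehand for genomic DNA, on the difference and its permutation p, were met on both WT arrays. They do not single it out, so genomic DNA remains open, as does any other difference that follows gene order. Higher transcription of dim genes with WT NusA cannot be told apart. These genes lay 3.45 and 2.32 above the mutants in the scanner files of the WT arrays but 3.43 and -0.442 in the deposited values. Their choice for low mutant values also tends by itself to place WT above the mutants.

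The deposited values of WT replicate 2 departed from their scanner file. A copy of another array of this series was argued against, since their highest correlation with any of its scanner files was 0.976. The other columns reached 0.998 to 1.00 with their own. A copy of an array outside the series could not be checked. Whether the scanner file might hold the deposited profile plus signal like that of WT replicate 1 cannot be told apart. Such a mixture left a residual SD of 0.431 when fitted on the linear scale and 0.202 on the log2 scale, where the R258C arrays differed by 0.258. The deposited values with a constant left 0.499. No biological explanation was tested.

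Camera called the lists of heat shock and pyrimidine genes higher in G181D than in WT, though not with an estimated correlation (adjusted p = 0.439 and 0.574), and 14 of 21 and 4 of 15 members rose. The narrow range of the WT arrays was examined as the cause with the mutant arrays alone, which were measured in the same scan. Over the whole fixed lists the G181D arrays lay above R258C by medians of 2.09 and 1.72 for heat shock. For pyrimidine biosynthesis the medians were 1.75 and 1.78, where R258C against G181D had a median of all genes of -0.37. The lists thus differed between the mutants without the WT arrays. This does not place either mutant against WT, and the same G181D arrays had led to the choice of these lists, so the narrow range stays open for the WT comparison. In these lists 18 of 21 and 13 of 15 members lay above both R258C arrays on both G181D arrays. A difference in growth or handling between the cultures of the mutants remains open and was not tested.

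A hypothesis written before its test was that signal is lost along operons more in R258C than in G181D, as premature termination could bring about. Of 26 fixed operons 7 had a negative and 19 a positive slope of R258C minus G181D with gene position (sign test, exact p = 0.029; median slope 0.136), which is the direction opposite to the hypothesis. The bound set beforehand against the hypothesis, a p of at least the threshold, did not cover the opposite direction. The direction argues against the hypothesis for these arrays only. The sign test counts operons of the same arrays as independent, so its p measures the spread among operons and not between arrays or cultures. Against WT the slopes were 7 negative and 19 positive in R258C (exact p = 0.029; median 0.0624) and 15 and 11 in G181D (exact p = 0.557).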
